A study of Mus musculus with 22 samples.

How the data were processed

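RNA was measured in left ventricular tissue of FVB mice. The mice were wild type (WT) or carried a VCP transgene (VCP TG), and had either a sham operation or transverse aortic constriction (TAC), a surgical narrowing of the aortic arch that loads the left ventricle with pressure. The 22 libraries fall into 6 groups. At 2 weeks after surgery there were 4 WT sham, 4 VCP TG sham, 4 WT TAC and 3 VCP TG TAC libraries. At 5 weeks there were 4 WT TAC and 3 VCP TG TAC libraries, and no sham group was analysed here. Per the labels' protocols, total RNA was extracted with a Qiagen miRNeasy kit and libraries were made with an Illumina TruSeq Stranded mRNA kit.

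The authors deposited 1 table for the 15 libraries of 2 weeks and another for the 7 libraries of 5 weeks, each with 1 column per library and 30735 Ensembl genes. The deposited values are transcripts per 1000000 (TPM), which was read from the values: each column sums to 1000000. Trimmomatic 0.35, kallisto 0.43.1, STAR 2.5.4b, DESeq2 and the genome build GRCm38 are listed in the submitters' processing notes with no role or order. Which of them made the tables, and with which annotation release, is not given in the sources used here. TPM keeps no record of read number, so the depth of each library is unknown and no interval from counts can be given. A low TPM can rest on few reads in any library. TPM also sums to a fixed total, so a rise of abundant transcripts lowers all other values of that library. The 13 mitochondrially encoded genes took 27.9% to 72.9% of TPM in a library.

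Gene names, types and positions came from GENCODE release M21 on GRCm38, in which 30074 of the 30735 identifiers were found. The 661 others took 1.90% to 25.9% of TPM in a library, of which ENSMUSG00000089855 alone took 1.47% to 23.3%. Each column was matched to a sample by its name, and no column was left without a sample. No pair of libraries held identical values, and the highest correlation between libraries of a table was 0.974. The labels do not say which libraries came from which animal, so p-values measure the spread between these libraries.

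The main test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with 1 mean per group, a variance trend and robust empirical Bayes moderation. Genes with at least 1 TPM in at least 3 libraries were tested, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A gene at 0 outside a group of 3 libraries could enter only through that group. Groups at 0 also lower its pooled spread, so p-values of such genes can be too small. The 4 groups of the 2-week table were fitted together (15540 genes), the 2 groups of the 5-week table together (13986 genes), and all 6 groups for the difference between the time points (16347 genes). Time point and table cannot be told apart, so the limma and camera tests compared only the genotype difference within each table between them. The grouping of Vcp levels and the closing remark on receptor genes did view levels over both tables, without a test. Log2 fold changes on the TPM + 1 scale understate the change of low genes. Errors are SD for TPM and standard errors for log2 fold changes. Count models were planned in case of counts and were not used, since the values are not counts. The comparisons, the tests, the gene lists and the rule for named genes were fixed before the data were examined.

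The text names genes by that rule: Vcp in every library; Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2 and Col1a1; up to 8 genes per direction with the largest log2 fold change among those past the threshold with a mean of at least 1 TPM and no overlap between the groups, without predicted names; and up to 4 members of each list that passed its test or is described. The 41 gene lists cover pathways of the loaded heart, proteostasis and 12 sets of markers of other cell types and tissues. Each list was tested with camera in limma with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, which asks if the genes of a list move, on balance, one way. No list passed with an estimated correlation or with fry in any of the 7 comparisons. A list's shift is its median log2 fold change minus that of all genes tested, because the median of all genes itself moved, by up to 0.22 in a comparison. Quantile normalization brought that median to between -0.05 and 0.01. Counts of list members are given over all genes and adjusted over the list alone.

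Replicate numbers recur between groups, and their meaning is not given in the sources used here. In the sham comparison, deviations from the group means of same-numbered libraries correlated by 0.107 to 0.260 across genes in all 4 pairs. On the evidence of the data alone, a second fit therefore treated these numbers as pairs. Sham values in the text come from the fit without pairs unless said otherwise. With the replicate number as a block, limma called 0 genes in that comparison, as without it, and 7 of the 8 lists that passed there passed again.

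The steps were tested on simulated data with each gene's real mean and pooled spread, independent normal noise and 200 changed genes. The changed genes were drawn from those of higher mean, and every group had the same spread. In the real 2-week groups the median SD ran from 0.193 to 0.580, so the shares recovered hold for the simulated setting only. The table of 15 libraries recovered 33% of genes changed 2-fold and 94% of those changed 4-fold for VCP TG against WT in sham. These shares were 30% and 96% for TAC in WT, 19% and 88% for TAC in VCP TG, 21% and 91% for VCP TG against WT at 2 weeks TAC, and 4% and 59% for the difference between the TAC effects. At 5 weeks they were 33% and 87%, for the difference between time points 7% and 61%, and for the 8 WT libraries fitted alone 67% and 97%.

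Other settings foreseen in the design were quantile normalization, limma without trend, no filter on low values, a minimum of 5 TPM, a minimum fold of 1.5, pseudocounts of 0.1 and 5, the replicate block, only the 2 groups compared, and leaving out each library in turn. Added after seeing the data were rescaling to nuclear protein-coding genes, leaving out libraries whose Vcp goes against the label, leaving out libraries with 300 TPM or more of the atrial gene Myl7, a covariate for the level of olfactory and vomeronasal receptor genes, a test of named protein-coding genes only, the gene lists leaving out each library in turn, and centring of each library in the fit of 8 WT libraries. Tests of GC content, transcript length, read background and other splits of the libraries are in the closing observations. Plots were made with matplotlib 3.10.9 in Python 3.11.15.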

Results

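Transcript levels were measured in 22 left ventricular libraries of mice that were wild type (WT) or carried a VCP transgene (VCP TG). VCP, valosin-containing protein, is an ATPase that extracts ubiquitinated proteins from membranes and complexes for degradation. At 2 weeks there were sham-operated hearts (4 WT, 4 VCP TG) and hearts under pressure overload from transverse aortic constriction, TAC (4 WT, 3 VCP TG). At 5 weeks there were TAC hearts alone (4 WT, 3 VCP TG). The series asks how VCP bears on cardiac hypertrophy and dysfunction under pressure overload. Values are in TPM (mean ± SD) and changes in log2 of TPM + 1 (± standard error). Adjusted p-values are from limma, or for gene lists from its camera test. The read depth of the libraries is unknown. Between 11629 and 16813 genes reached 1 TPM.

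Vcp itself (ENSMUSG00000028452, chromosome 4, 42979963 to 43000507, minus strand) checks the genotype labels. In sham hearts it stood at 62.1 ± 15.4 TPM in WT (n = 4) and 126 ± 53.4 in VCP TG (n = 4). At 2 weeks TAC it stood at 66.2 ± 35.0 TPM in WT (n = 4) and 137 ± 13.2 in VCP TG (n = 3). At 5 weeks TAC the values were 84.9 ± 35.8 TPM in WT (n = 4) and 88.4 ± 43.0 in VCP TG (n = 3). The log2 differences between genotypes were 0.94 ± 0.33 in sham (limma adjusted p = 1), 1.16 ± 0.35 at 2 weeks TAC (adjusted p = 0.174) and 0.01 ± 0.45 at 5 weeks TAC (adjusted p = 0.998), so none passed the test.

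The library labelled WT 2 weeks TAC replicate 1 held 119 TPM of Vcp, against 47.7 to 50.3 in the other 3 of its group. The libraries labelled WT 5 weeks TAC replicates 2 and 3 held 123 and 107 TPM. The library labelled VCP TG 5 weeks TAC replicate 3 held 39.1 TPM and the library labelled VCP TG sham replicate 1 held 89.1. After rescaling to nuclear protein-coding genes, 11 libraries lay at 46.4 to 67.9 TPM and 11 at 106 to 160, and these 5 libraries lay with the other genotype. Grouped in the same way on TPM as deposited, VCP TG sham replicate 1 lay with its own genotype, the other 4 stayed out of place, and WT sham replicate 2 (82.6 TPM) and VCP TG sham replicate 4 (73.5 TPM) lay with the other genotype. Every direction given below between VCP TG and WT follows the labels. The libraries said below to have a Vcp level against the label are the 5 on rescaled values.

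**Figure D1:**
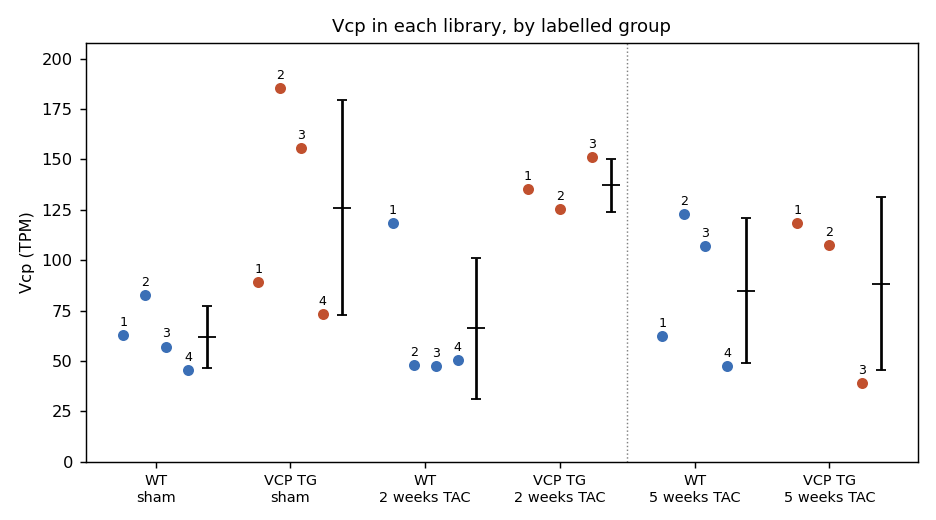
Vcp in TPM (vertical axis) in each of the 22 libraries by labelled group, WT in blue and VCP TG in red, with replicate numbers, and the group mean with its SD in black; the dotted line parts the 2-week table from the 5-week table. The library labelled WT 2 weeks TAC replicate 1 sits at 119 TPM, near the 125 to 151 of the VCP TG 2 weeks TAC libraries, and the library labelled VCP TG 5 weeks TAC replicate 3 sits at 39.1.

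Atrial transcripts varied between libraries of the same group. Myl7, the atrial myosin light chain, stood at 2269 TPM in VCP TG sham replicate 3, 394 in VCP TG sham replicate 4, 1546 in the library labelled WT 2 weeks TAC replicate 1 and 951 in VCP TG 2 weeks TAC replicate 2. In the 4 WT sham libraries it lay between 0.773 and 55.6 TPM. Nppa, the atrial natriuretic peptide, which ventricles also make under load, followed the same libraries, with 4864 TPM in VCP TG sham replicate 3 and 5174 in the library labelled WT 2 weeks TAC replicate 1. Its values elsewhere in the WT 2 weeks TAC group were 32.5 to 88.6 TPM.

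**Figure D2:**
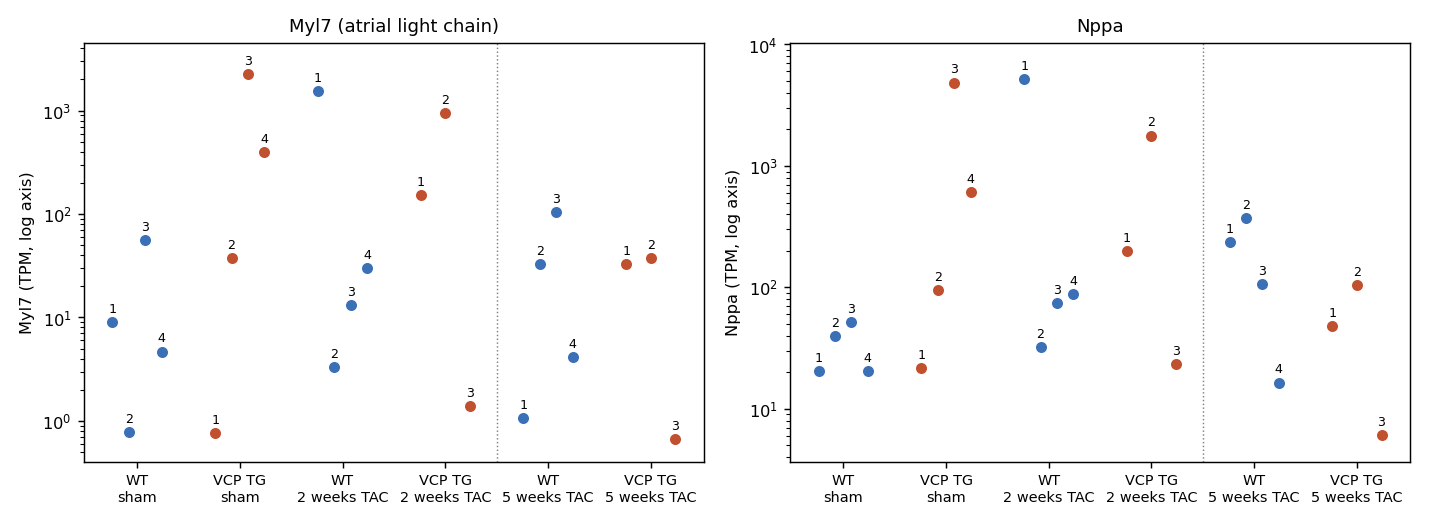
Myl7 (left) and Nppa (right) in TPM on log axes in each library by labelled group, with replicate numbers, WT in blue and VCP TG in red. VCP TG sham replicate 3 (Myl7 2269 TPM) and the library labelled WT 2 weeks TAC replicate 1 (1546 TPM) stand highest for both genes.

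Genes not thought to be used by the ventricle were taken as a gauge of background, which was not shown to be the source of their signal. Of 1657 olfactory and vomeronasal receptor genes, 26.1 ± 7.89% were above 0 in WT sham libraries, 46.4 ± 16.1% in VCP TG sham, 69.5 ± 10.1% in WT 2 weeks TAC and 90.8 ± 4.71% in VCP TG 2 weeks TAC. Their mean level was 0.0779 ± 0.0170 TPM in WT sham, 0.157 ± 0.117 in VCP TG sham, 0.180 ± 0.0436 in WT 2 weeks TAC and 0.570 ± 0.291 in VCP TG 2 weeks TAC. At 5 weeks TAC it was 0.211 ± 0.0916 TPM in WT and 0.347 ± 0.164 in VCP TG. In the 2-week table each VCP TG TAC library (0.337 to 0.895 TPM) lay above every other library (highest 0.327). The WT 2 weeks TAC libraries (lowest 0.124 TPM) also lay above every WT sham library (highest 0.0888). Where VCP TG TAC libraries of 2 weeks are compared, or WT TAC with WT sham, a covariate for this level cannot tell background from a group effect.

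**Figure D3:**
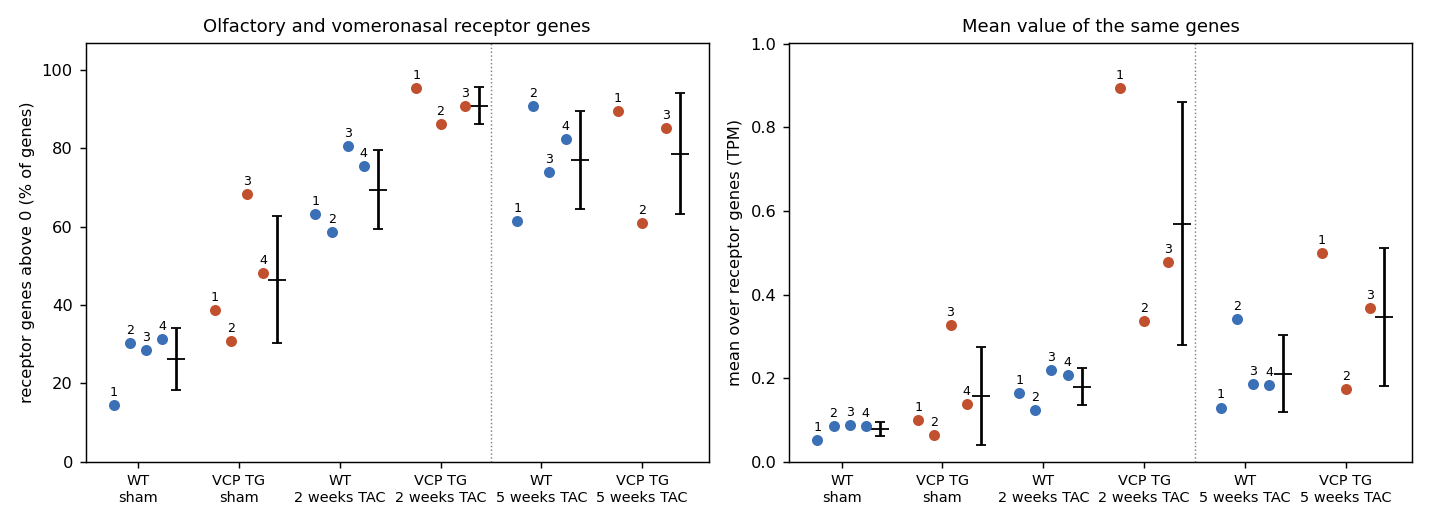
Percent of 1657 olfactory and vomeronasal receptor genes above 0 (left) and their mean TPM (right) in each library by labelled group, with replicate numbers and the group mean with its SD in black. WT sham libraries lie between 14.4% and 31.4%, and VCP TG 2 weeks TAC libraries between 86.1% and 95.5%.

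The effect of the transgene without load was asked in sham hearts, VCP TG against WT (4 libraries each). Markers of red blood cells were higher in VCP TG, with a median shift of 2.02 over 6 measured genes and all 6 above the median of all genes (camera adjusted p = 9.67e-10; adjusted p = 0.446 with an estimated correlation). The beta-globin genes Hbb-bt (3.04 ± 0.83) and Hbb-bs (2.85 ± 0.79) passed when adjusted over the list alone, 2 of 6 members, with every VCP TG library above every WT library. Hbb-bs was 298 ± 426 TPM in VCP TG and 25.7 ± 18.8 in WT, and VCP TG sham replicate 3 alone held 936 TPM. Markers of atrial tissue were higher, with a median shift of 3.01 over 11 genes (adjusted p = 2.75e-07; 0.973 with an estimated correlation), among them Sln (4.12 ± 2.58) and Kcnj3 (1.35 ± 0.57), none passing alone, and without the libraries rich in atrial genes that call was lost.

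Glycolysis and glucose uptake genes were lower in VCP TG sham hearts, 21 of 22 lying below the median of all genes (shift -0.31; adjusted p = 0.000333; 0.973 with an estimated correlation). Values were -0.73 ± 0.34 for the phosphofructokinase Pfkp and -0.56 ± 0.32 for the hexokinase Hk2, and no member passed alone. Without VCP TG sham replicate 4, where 72.9% of TPM is mitochondrial, they were -0.33 and -0.17. Endothelial markers were lower by a shift of -0.45 over 14 genes (adjusted p = 0.00105), with Ly6c1 at -0.97 ± 0.32 and Cdh5, the endothelial cadherin, at -0.65 ± 0.28 (-0.71 and -0.29 without that library). Muscle atrophy genes and ubiquitin ligases (-0.29, 17 genes, adjusted p = 0.0248) and mitochondrial biogenesis and dynamics genes (-0.23, 23 genes, adjusted p = 0.0361) were lower too, the second with the nuclear receptor Esrra at -0.93 ± 0.41 (-0.34 without that library, where the list call was lost). The calls of these 4 lists and of the immediate early genes below were lost without the libraries rich in atrial genes. Of VCP TG sham that fit kept replicates 1 and 2 alone, and 13 lists passed in it. Cytosolic ribosomal proteins were higher by 0.22 over 37 genes (adjusted p = 0.00701), with Rps24 at 0.81 ± 0.32, a call lost without the library whose Vcp goes against the label. Immediate early genes, which respond within minutes to stimuli, were higher by 0.58 over 20 genes (adjusted p = 0.0377), with Fos at 1.83 ± 0.82. With the replicate block the immediate early genes no longer passed (camera adjusted p = 0.0748). Their call was also lost without VCP TG sham replicate 3, without WT sham replicate 1 and without WT sham replicate 3. The receptor genes as a covariate ended the calls of glycolysis, atrophy, mitochondrial biogenesis and immediate early genes. With an estimated correlation the adjusted p of each of these lists was 0.973.

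By limma 0 of 15540 genes passed between VCP TG and WT in sham, the smallest adjusted p being 0.735, and 616 had an unadjusted p under 0.05. The replicate block also gave 0 genes, with 743 at an unadjusted p under 0.05, and limma without trend gave 0, with 614. The groups did not overlap in 161 genes (1.04%), against the 2.86% that chance gives. Here and below the chance share is an expectation with no spread, and genes are not independent. Nppa (3.16 ± 1.96), Nppb (0.59 ± 0.72), Myh6 (-0.29 ± 0.31), Myh7 (-0.38 ± 0.34), Acta1 (-0.32 ± 0.57), Atp2a2 (0.28 ± 0.29) and Col1a1 (0.28 ± 0.50) did not pass. Without VCP TG sham replicate 4, Myh6 (0.12), Myh7 (0.06) and Acta1 (0.06) changed sign.

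The response to pressure overload was asked in WT hearts, 2 weeks TAC against sham (4 libraries each). Immediate early genes were lower at 2 weeks TAC, all 20 lying below the median of all genes (shift -1.04; camera adjusted p = 4.44e-05; adjusted p = 0.932 with an estimated correlation). Values were -1.99 ± 0.82 for the zinc finger factor Egr1 and -1.70 ± 0.65 for Zfp36, which speeds the decay of cytokine mRNA. Macrophage markers were higher by 0.66 over 13 genes (adjusted p = 0.000146; 0.932 with an estimated correlation), among them the lysozyme Lyz2 (1.11 ± 0.34) and Adgre1 (0.69 ± 0.24), and none passed alone. Fatty acid uptake and oxidation genes were lower by -0.16 over 30 genes (adjusted p = 0.0324), and 3 passed when adjusted over the list alone, among them the fatty acid transporter Slc27a1 (-1.32 ± 0.37) and Acads (-0.86 ± 0.27). For both, every TAC library lay below every sham library.

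Further lists passed in WT hearts at 2 weeks TAC. Cytosolic ribosomal proteins were higher by 0.36 over 37 genes (adjusted p = 0.000259), with Rps24 (1.22 ± 0.32) passing over the list alone, and nuclear-encoded respiratory chain subunits by 0.22 over 40 genes (adjusted p = 0.00660). In the second list Cox7a1 stood at 0.94 ± 0.32 and Uqcrc1, of complex III, at -1.13 ± 0.37. Cell cycle genes were higher by 0.21 over 28 genes (adjusted p = 0.0231), with the proliferation marker Mki67 at 0.66 ± 0.32. Glycolysis and glucose uptake genes were lower by -0.21 over 22 genes (adjusted p = 0.0232), with Hk2 at -0.94 ± 0.32. Endothelial markers were lower by -0.33 over 14 genes (adjusted p = 0.0324), with Esam (-1.22 ± 0.40) and the VEGF receptor Flt1 (-0.91 ± 0.30) passing over the list alone. Markers of mesothelium and valves (0.98 over 7 genes, adjusted p = 0.0119) and of atrial tissue (1.97 over 11 genes, adjusted p = 0.00163) were higher too, the first with Upk1b, Msln and Upk3b passing over the list alone. The calls of both, and of glycolysis and fatty acid genes, were lost without the libraries rich in atrial genes, of which the library labelled WT 2 weeks TAC replicate 1, whose Vcp also goes against the label, is in this comparison. Respiratory chain and mesothelium calls were lost under quantile normalization, and those of atrial, cell cycle, glycolysis, endothelial and fatty acid genes with the receptor genes as a covariate. The receptor level parted the WT groups too, with at most 0.0888 TPM in sham and at least 0.124 at 2 weeks TAC. The covariate therefore cannot tell background from an effect of load here. With an estimated correlation the adjusted p of each list was 0.932.

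In the main test, which pools the spread of all 4 groups, limma called 0 of 15540 genes for WT TAC against sham. The smallest adjusted p was 0.0660, and 1773 genes had an unadjusted p under 0.05; limma without trend also gave 0, with 1761. The groups did not overlap in 2520 genes (16.2%), against 2.86% by chance. A difference between libraries can part many genes at once, so this share alone does not show an effect of load. Myh7, the slow myosin heavy chain, stood at 411 ± 55.9 TPM in sham and 188 ± 29.1 at 2 weeks TAC (-1.12 ± 0.34, adjusted p = 0.327), and Myh6 at 6098 ± 734 and 3687 ± 378 (-0.72 ± 0.31, adjusted p = 0.399). In both, the 4 TAC libraries lay below the 4 sham libraries. Nppa (2.54 ± 1.96), Nppb (0.25 ± 0.72), Acta1 (-0.97 ± 0.57), Atp2a2 (0.16 ± 0.29) and Col1a1 (0.26 ± 0.50) did not pass.

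The spread that the test pools differed between groups. The median SD of log2 values over genes was 0.312 in WT sham and 0.208 in WT 2 weeks TAC, against 0.580 in VCP TG sham. Fitted alone, as foreseen before the values were seen, the 8 WT libraries gave 964 of 13709 genes past the threshold, 99 higher and 865 lower at 2 weeks TAC. With VCP TG sham left out of the 4-group fit 1608 genes passed, and with VCP TG 2 weeks TAC left out 0. The gene values below come from the fit of 8 libraries, and each gene named had no overlap between the groups except Junb and Zfp36. Of all genes tested there, 6.31% were called lower, the rate against which the counts per list stand. By camera in this fit glycolysis (adjusted p = 0.0216) and immediate early genes (adjusted p = 0.000458) were lower as lists. Ribosomal protein and macrophage genes (adjusted p = 0.000458 each), respiratory chain (0.00126), atrial (0.00130) and cell cycle genes (0.0216) were higher against the other genes. None of the 7 passed with an estimated correlation (adjusted p = 0.846).

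Single genes of excitation and calcium handling fell in that fit, 7 of 33 measured (10 adjusted over the list alone), while the list as a whole did not pass (camera adjusted p = 0.182). Among the 7 were the K-ATP channel pore Kcnj11 (-1.41 ± 0.21; 32.5 ± 6.98 TPM in sham, 11.6 ± 2.60 at 2 weeks TAC), the L-type calcium channel Cacna1c (-1.04 ± 0.16) and the dyad protein Jph2 (-1.01 ± 0.19). Of 23 sarcomere and Z-disc genes 5 fell (7 over the list alone) and the list did not pass (adjusted p = 0.0565), among them Tcap (-0.95 ± 0.24), Mybpc3 (-0.83 ± 0.19), Ldb3 (-0.70 ± 0.17) and Tpm1 (-0.67 ± 0.18). Myh7 (-1.12 ± 0.18, adjusted p = 0.0136), Myh6 (-0.72 ± 0.17, adjusted p = 0.0325) and Ankrd23 (-0.90 ± 0.21) fell among 19 genes of the hypertrophy and fetal programme, a list that did not pass (adjusted p = 0.496).

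Of 23 regulators of mitochondrial biogenesis 5 fell (10 over the list alone) and the list did not pass (adjusted p = 0.0587), among them the nuclear receptors Esrra (-1.02 ± 0.16; 20.2 ± 2.88 TPM in sham, 9.47 ± 1.18 at 2 weeks TAC) and Esrrb (-0.77 ± 0.17), the deacetylase Sirt3 (-0.89 ± 0.17) and Perm1 (-0.86 ± 0.21). In fatty acid uptake and oxidation Slc27a1 (-1.32 ± 0.17), Mlycd (-0.89 ± 0.21) and Acads (-0.86 ± 0.18) fell, 3 of 30 (9 over the list alone), in a list that did not pass (adjusted p = 0.150). Of 22 glycolysis and glucose uptake genes 5 fell (6 over the list alone), with the phosphofructokinase Pfkm (-0.95 ± 0.19), the hexokinase Hk2 (-0.94 ± 0.20), the pyruvate kinase Pkm (-0.86 ± 0.16) and the insulin-responsive glucose transporter Slc2a4 (-0.79 ± 0.21). Of 40 respiratory chain subunits, Uqcrc1 fell (-1.13 ± 0.20) and Cox7a1 rose (0.94 ± 0.20; 1726 ± 339 TPM in sham, 3299 ± 600 at 2 weeks TAC).

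Growth and degradation genes included members that fell, in lists that did not pass (adjusted p = 0.605 for autophagy, 0.192 for mTOR and 0.197 for atrophy genes). These were the autophagy genes Atg4b (-1.01 ± 0.18), Atg13 (-0.96 ± 0.16), Atg9a (-0.86 ± 0.18) and Ulk1 (-0.71 ± 0.18), among 5 of 35 in the list (7 lower and 1 higher over the list alone), and Akt1s1 (-1.03 ± 0.17), Rptor (-0.73 ± 0.15), Akt1 and Mtor (-0.65 ± 0.18) of 26 mTOR and growth genes (10 over the list alone). The ubiquitin ligase genes Fbxo31 (-1.05 ± 0.23), Trim54 (-0.81 ± 0.21), Cblb and Trim55 (-0.68 ± 0.15) fell among 17 atrophy genes (5 over the list alone). Per1, a core repressor of the circadian clock (list adjusted p = 0.385), fell from 40.7 ± 11.7 to 11.8 ± 2.64 TPM (-1.68 ± 0.23), and Cry2 by -0.84 ± 0.22. Junb (-1.72 ± 0.45) and Zfp36 (-1.70 ± 0.42) fell among 19 immediate early genes (9 over the list alone). The NF-kappaB inhibitor Nfkbia (-1.62 ± 0.31) and the chemokine Cxcl1 (-1.78 ± 0.46) fell among 22 inflammatory genes, a list that did not pass (camera adjusted p = 0.379). Endothelial Esam (-1.22 ± 0.18), Flt1 (-0.91 ± 0.23) and Tie1 (-0.73 ± 0.19) fell in a list that did not pass (adjusted p = 0.0587), and so did Sox17 (-1.77 ± 0.39) and the amino acid transporter Slc7a5 (-1.72 ± 0.36).

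**Figure D4:**
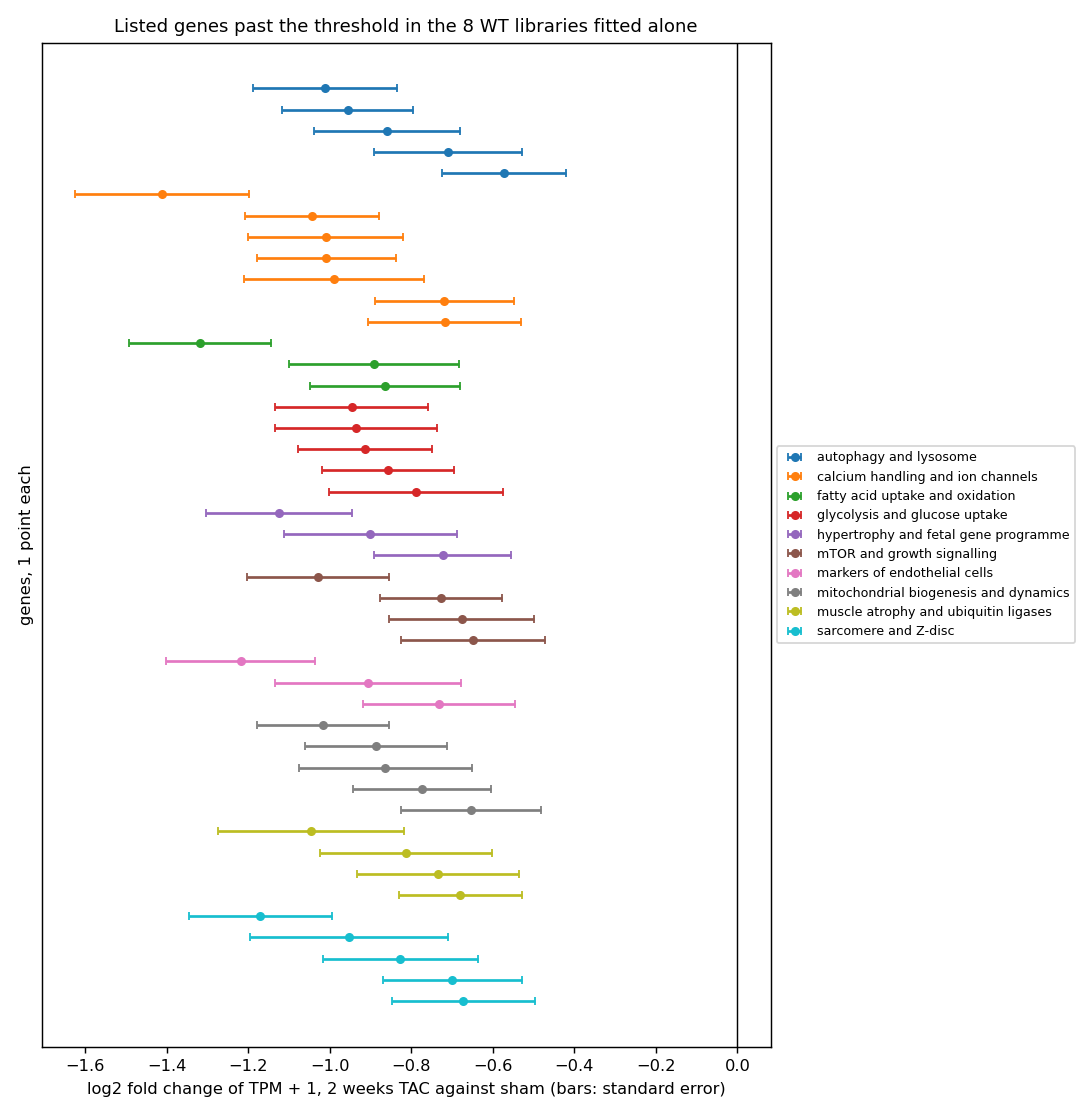
Log2 fold change of TPM + 1 (horizontal axis, bars are standard errors) at 2 weeks TAC against sham in the 8 WT libraries fitted alone, for 44 genes past the threshold in the 10 gene lists with at least 3 such genes, coloured by list, 1 point per gene. All 44 lie below 0, the lowest being Kcnj11 at -1.41. Of the 964 genes called in that fit 865 were lower and 99 higher. Lists with fewer called genes are not shown, among them the respiratory chain, in which Cox7a1 rose.

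Genes that rose in the same fit included Rab5if (1.45 ± 0.29; 20.3 ± 9.88 TPM in sham, 52.6 ± 4.29 at 2 weeks TAC), the eye lens gamma-crystallin Crygn (1.46 ± 0.21) and Chil3, a chitinase-like macrophage product (1.14 ± 0.22). Rnaset2b (2.75 ± 0.39) and Sly (1.67 ± 0.24) also rose, but both have near-identical copies between which reads can be shared. The immunoglobulin segment Ighv1-67 (1.46 ± 0.27), the zinc finger gene Zfp600 (1.28 ± 0.32) and the vomeronasal receptor pseudogene Vmn2r-ps104 (1.18 ± 0.24) rose too. Of the 99 genes that rose, 48 were predicted or unnamed, while the share of receptor genes above 0 went from 26.1% to 69.5%. Leaving out 1 library moved the 964 calls to between 49 (without WT 2 weeks TAC replicate 3) and 2148 (without WT sham replicate 4). They were 70 without WT sham replicate 3, 423, 178 and 225 without WT 2 weeks TAC replicates 1, 2 and 4. Quantile normalization gave 635 genes, 324 higher and 311 lower, of which 377 were among the 964. After each library's trend with GC content was removed, 145 genes passed, 102 higher and 43 lower, and of the 854 genes with a GC value called lower before, 40 were still called.

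The same load was asked in VCP TG hearts, 2 weeks TAC (3 libraries) against sham (4 libraries). Immediate early genes were lower at 2 weeks TAC, all 20 below the median of all genes (shift -1.58; camera adjusted p = 1.69e-17; adjusted p = 0.859 with an estimated correlation). Over the list alone 9 of 20 passed. Egr1 stood at 116 ± 124 TPM in sham and 3.80 ± 0.790 at 2 weeks TAC (-4.03 ± 0.88), Fos at 43.7 ± 68.3 and 0.819 ± 0.0427 (-3.47 ± 0.88), and the nuclear receptor Nr4a1 at -3.15 ± 1.03. Btg2 (-2.65 ± 0.71) and Ier2 (-2.17 ± 0.63) followed, and for these 5 genes every TAC library lay below every sham library. The atrial-rich VCP TG sham replicates 3 and 4 are among those sham libraries, and the list passed without them, but not with an estimated correlation or with fry.

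Red blood cell markers were lower at 2 weeks TAC in VCP TG hearts by -1.71 over 6 genes (adjusted p = 0.000107), with Hbb-bs at -2.15 ± 0.86, and this call was lost without the libraries rich in atrial genes. Genes of protein folding were lower: the unfolded protein response by -0.28 over 27 genes (adjusted p = 0.000261), with the endoplasmic reticulum chaperone Hsp90b1 at -0.54 ± 0.27 and Ppp1r15a at -0.95 ± 0.41, and heat shock proteins by -0.23 over 24 genes (adjusted p = 0.000434), with Hsph1 at -0.90 ± 0.37. Circadian clock genes were lower by -0.20 over 18 genes (adjusted p = 0.00528), with Per1 at -1.25 ± 0.51 and Per2 at -0.66 ± 0.32. The hypertrophy and fetal programme was lower by -0.21 over 20 genes (adjusted p = 0.00733), with Nmrk2 at -0.83 ± 0.35 and the stretch-responsive Ankrd1 at -0.74 ± 0.41. Smooth muscle and pericyte markers (-0.17 over 13 genes, adjusted p = 0.0213), extracellular matrix (-0.14 over 32 genes, adjusted p = 0.0254) and respiratory chain subunits (-0.09 over 40 genes, adjusted p = 0.0244) were lower by less. Cell cycle genes were higher by 0.21 over 28 genes (adjusted p = 0.0208), with the thymidylate synthase Tyms (1.21 ± 0.32) passing over the list alone. Each of these lists had an adjusted p of 0.859 with an estimated correlation. Without the libraries rich in atrial genes the calls of clock, smooth muscle and matrix genes were lost, and without the library whose Vcp goes against the label those of cell cycle and respiratory chain genes. The fit without atrial-rich libraries kept only VCP TG sham replicates 1 and 2 and VCP TG TAC replicates 1 and 3. In it 24 lists passed, 6 of the 10 among them, so the losses cannot show an atrial origin. Under quantile normalization cell cycle, respiratory chain and matrix genes no longer passed. The receptor genes as a covariate ended the calls of heat shock, clock, hypertrophy, cell cycle and smooth muscle genes. With the receptor genes as a covariate the respiratory chain went the other way (0.64, camera adjusted p = 4.80e-13). With that covariate 18 lists passed, 4 of the 10 in the same direction. Its level parts the 2 groups, so it cannot tell background from an effect of load.

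By limma 120 of 15540 genes passed in VCP TG hearts, 119 higher and 1 lower at 2 weeks TAC, and 1363 had an unadjusted p under 0.05. Of the 120, 53 were pseudogenes, 78 had predicted names or none, 7 were receptor genes, 8 were immunoglobulin genes and 27 were named nuclear protein-coding genes. In 63 of them the mean of both groups lay below 5 TPM. BC023105, a processed pseudogene (chromosome 18, 60441765 to 60442980), rose from 0.736 ± 0.531 to 6.46 ± 2.03 TPM (2.12 ± 0.29, adjusted p = 0.00167). The beta-globin pseudogene Hbb-bh0 (chromosome 7, 103850020 to 103850148) was listed at 0 in all 4 sham libraries and stood at 3.60 ± 0.406 TPM at 2 weeks TAC (adjusted p = 0.00015). Hbb-bh0 entered the test only through these TAC libraries, so its p can be too small. The spermatid genes Sly (1.84 ± 0.36, adjusted p = 0.0294) and Srsy (1.82 ± 0.31, adjusted p = 0.0124) on chromosome Y, the urinary protein gene Mup9 (2.07 ± 0.46), the pheromone receptor Vmn2r55 (1.91 ± 0.43) and the immunoglobulin segment Ighv8-8 (1.97 ± 0.39) rose as well. Ighv1-12 was listed at 0 in all 4 sham libraries and stood at 3.43 ± 2.22 TPM. Most of these belong to families of near-identical copies. In each, all 3 TAC libraries lay above all 4 sham libraries. The gene that fell, named after its values were seen, was the predicted gene Gm20594 (17161 ± 2276 TPM in sham, 7555 ± 986 at 2 weeks TAC).

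The count of 120 moved to 0 with the receptor gene level as a covariate, to 7 among named protein-coding genes and to 2 with a pseudocount of 0.1, and was 1 without VCP TG 2 weeks TAC replicate 1, 753 without VCP TG sham replicate 3 and 8 to 196 without any of the other 5. Quantile normalization gave 69 higher and 15 lower. The groups did not overlap in 625 genes (4.02%), against 5.71% by chance. Nppa (-0.47 ± 2.12), Nppb (-1.17 ± 0.78), Myh6 (-0.09 ± 0.33), Myh7 (-0.40 ± 0.37), Acta1 (0.13 ± 0.61), Atp2a2 (-0.09 ± 0.31) and Col1a1 (-0.46 ± 0.54) did not pass.

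The effect of the transgene under load was asked at 2 weeks TAC, VCP TG (3 libraries) against WT (4 libraries). Nuclear-encoded respiratory chain subunits were lower in VCP TG relative to other genes, 37 of 40 below the median of all genes (shift -0.35; camera adjusted p = 7.08e-08; adjusted p = 0.870 with an estimated correlation). Cox8b stood at -0.55 ± 0.29 and Cox7b, both of cytochrome c oxidase, at -0.51 ± 0.28, and no member passed alone. All 13 mitochondrially encoded subunits lay below that median too (shift -0.31; adjusted p = 0.000271), with mt-Atp8 at -0.60 ± 0.29, and 16 of 22 tricarboxylic acid cycle genes (shift -0.20; adjusted p = 0.0266), with Sdha at -0.38 ± 0.30. Extracellular matrix genes were lower by -0.33 over 32 genes (adjusted p = 2.41e-05), with elastin, Eln, at -0.74 ± 0.49 and Fbn1 at -0.45 ± 0.33.

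Protein folding genes were lower in VCP TG at 2 weeks TAC: heat shock proteins by -0.33 over 24 genes (adjusted p = 0.000141), with the mitochondrial chaperonin Hspe1 at -0.49 ± 0.26, and the unfolded protein response by -0.26 over 27 genes (adjusted p = 0.000280), with Dnajb9 at -0.57 ± 0.26. Cytosolic ribosomal proteins were lower by -0.24 over 37 genes (adjusted p = 0.000306), while Rps18 stood at 0.92 ± 0.30. Macrophage markers (-0.27 over 13 genes, adjusted p = 0.00503; Lyz2 -0.71 ± 0.37), smooth muscle and pericyte markers (-0.30 over 13 genes, adjusted p = 0.0206; Tagln -0.54 ± 0.38) and immediate early genes (-0.18 over 20 genes, adjusted p = 0.0469; Myc -0.83 ± 0.48) were lower as well. With an estimated correlation the adjusted p of each of these lists was 0.870. The median of all genes lay at 0.16, so these are shifts against the other genes. Matrix, macrophage and immediate early calls were lost without the library whose Vcp goes against the label, and macrophage, smooth muscle and immediate early calls without the libraries rich in atrial genes. Under quantile normalization 4 of the 10 lists passed, and heat shock, mitochondrially encoded, ribosomal, smooth muscle, tricarboxylic acid cycle and immediate early genes did not. With the receptor genes as a covariate respiratory chain (0.28, adjusted p = 2.42e-05) and tricarboxylic acid cycle genes (0.40, adjusted p = 1.12e-05) were higher, not lower, and heat shock, mitochondrially encoded and ribosomal genes did not pass. With that covariate 19 lists passed. Its level parts the 2 groups, so it cannot tell background from an effect of the genotype.

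By limma 14 of 15540 genes passed, all higher in VCP TG at 2 weeks TAC, and 1488 had an unadjusted p under 0.05. Of the 14, 12 were pseudogenes and 0 were named nuclear protein-coding genes. BC023105 rose from 1.01 ± 0.580 TPM in WT to 6.46 ± 2.03 in VCP TG (1.89 ± 0.29, adjusted p = 0.00541). Hbb-bh0, which entered the test only through the VCP TG TAC libraries, was listed at 0 in all 4 WT libraries and stood at 3.60 ± 0.406 TPM in VCP TG (limma adjusted p = 0.000299, which can be too small). In both genes all 3 VCP TG libraries lay above all 4 WT libraries. Leaving out the library labelled WT 2 weeks TAC replicate 2 gave 8 genes, VCP TG replicate 1 gave 1 and VCP TG replicate 3 gave 4. The groups did not overlap in 3391 genes (21.8%), against 5.71% by chance. A difference between libraries can part many genes at once, and the receptor level parts these groups. This share alone therefore does not show an effect of the genotype. Nppa (0.15 ± 2.12), Nppb (-0.83 ± 0.78), Myh6 (0.35 ± 0.33), Myh7 (0.34 ± 0.37), Acta1 (0.78 ± 0.61), Atp2a2 (0.03 ± 0.31) and Col1a1 (-0.44 ± 0.54) did not pass.

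Whether TAC acted differently in the genotypes was tested as the TAC effect in VCP TG minus that in WT. Cytosolic ribosomal proteins shifted less with TAC in VCP TG, 30 of 37 below the median of all genes (shift -0.53; camera adjusted p = 8.79e-07; adjusted p = 0.998 with an estimated correlation), with Rpl32 at -0.72 ± 0.34. Respiratory chain subunits had a shift of -0.42 over 40 genes (adjusted p = 1.81e-06), with Cox7a1 at -1.02 ± 0.47, heat shock proteins of -0.55 over 24 (adjusted p = 1.17e-05), with Hsph1 at -1.23 ± 0.50, and the unfolded protein response of -0.41 over 27 (adjusted p = 1.20e-05), with the secreted factor Manf at -1.24 ± 0.55. Fatty acid uptake and oxidation went the other way, with a shift of 0.22 over 30 genes (adjusted p = 0.0290), and Ucp3, a mitochondrial carrier, at 2.01 ± 0.57. Immediate early genes (-0.65, adjusted p = 0.000712; Btg2 -1.91 ± 0.97), the proteasome (-0.15, adjusted p = 0.0197; Psma2 -0.78 ± 0.39), extracellular matrix (-0.26, adjusted p = 0.0258) and macrophage markers (-0.25, adjusted p = 0.0290; Adgre1 -0.68 ± 0.35) had negative shifts. Red blood cell (-2.41, adjusted p = 6.42e-07) and atrial markers (-1.72, adjusted p = 0.000117), which are high in VCP TG sham replicate 3, did so too. Each list here had an adjusted p of 0.998 with an estimated correlation. Without the libraries rich in atrial genes the calls of atrial, immediate early, matrix, fatty acid and macrophage genes were lost, and without those whose Vcp goes against the label the proteasome and macrophage calls. Under quantile normalization respiratory chain, atrial, proteasome, matrix and macrophage genes no longer passed, and with the receptor genes as a covariate respiratory chain and proteasome genes did not.

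By limma 1 of 15540 genes passed the test of the difference, Hbb-bh0 (adjusted p = 0.034), and 779 genes had an unadjusted p under 0.05. Hbb-bh0 was listed at 0 in the 12 libraries of the other 3 groups, so it entered the test only through the VCP TG TAC libraries. The groups at 0 lower its spread, so its p can be too small. Of the 15 fits that left out 1 library 8 gave 0 genes, among them those without WT sham replicate 1 and without VCP TG TAC replicate 1. Nppa (-3.01 ± 2.88), Nppb (-1.42 ± 1.06), Myh6 (0.64 ± 0.45), Myh7 (0.72 ± 0.50), Acta1 (adjusted p = 0.873), Atp2a2 (-0.25 ± 0.42) and Col1a1 (-0.72 ± 0.74) did not pass. Across 15540 genes, which are not independent replicates, the TAC effects of WT and VCP TG correlated with r = 0.376 (rho 0.282).

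After longer load, 5 weeks TAC, VCP TG (3 libraries) was set against WT (4 libraries). Vcp did not differ between these labelled groups, so the directions below rest on labels that it goes against in 3 of the 7 libraries. Extracellular matrix genes were lower in VCP TG, 30 of 31 below the median of all genes (shift -0.46; camera adjusted p = 2.29e-08; adjusted p = 0.795 with an estimated correlation). Periostin, Postn, a matrix protein of activated fibroblasts, stood at -1.33 ± 0.55, Mfap4 at -1.29 ± 0.48, Col14a1 at -0.84 ± 0.22 and Col1a1 at -0.84 ± 0.34 (22.0 ± 6.63 TPM in WT, 12.3 ± 5.53 in VCP TG), and none passed alone. Fibroblast markers were lower by -0.35 over 14 genes (adjusted p = 0.00593), with Thy1 at -0.50 ± 0.20. Macrophage markers (-0.30 over 13 genes, adjusted p = 0.00593; C1qb -0.50 ± 0.18), inflammatory cytokines and chemokines (-0.18 over 23 genes, adjusted p = 0.00287; Ccl2 -1.22 ± 0.58) and interferon response genes (-0.22 over 27 genes, adjusted p = 0.00924; Bst2 -0.82 ± 0.28) were lower.

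Protein synthesis and folding genes were lower in VCP TG at 5 weeks TAC. Cytosolic ribosomal proteins shifted by -0.37, 34 of 37 below the median (adjusted p = 4.21e-09; Rpl3 -0.75 ± 0.23), and the unfolded protein response by -0.37 over 26 genes (adjusted p = 5.56e-06), with the asparagine synthetase Asns at -0.78 ± 0.19 and Herpud1 at 0.72 ± 0.22. Respiratory chain subunits (-0.23 over 40 genes, adjusted p = 7.38e-05; Cox6b1 -0.67 ± 0.31), the proteasome (-0.22 over 32 genes, adjusted p = 0.00234; Psmd12 -0.53 ± 0.24), heat shock proteins (-0.29 over 23 genes, adjusted p = 0.00445; Hspb3 -0.95 ± 0.30), immediate early genes (-0.26 over 20 genes, adjusted p = 0.0354; Atf3 -1.01 ± 0.45) and red blood cell markers (-0.40 over 5 genes, adjusted p = 0.0445; Hba-a2 -1.34 ± 0.88) were lower too. With an estimated correlation the adjusted p of each list was 0.795. Without the 3 libraries whose Vcp goes against the label, the calls of extracellular matrix, fibroblast, proteasome, inflammatory, heat shock and immediate early genes were lost. Those of ribosomal proteins, unfolded protein response, respiratory chain, interferon, macrophage and red blood cell genes stayed. That fit kept only WT replicates 1 and 4 and VCP TG replicates 1 and 2. The library labelled WT replicate 4 held 0.192 TPM of Ddx3y, a gene of chromosome Y. In the fit that left out this library alone, the interferon, macrophage and red blood cell calls were lost. Respiratory chain, heat shock, immediate early and red blood cell calls were lost under quantile normalization, and heat shock, interferon and red blood cell calls with the receptor genes as a covariate.

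By limma 1 of 13986 genes passed at 5 weeks TAC, and 628 had an unadjusted p under 0.05. It was the immunoglobulin pseudogene Igkv2-95-2 (chromosome 6, 68647415 to 68648121), listed at 0 in all 4 WT libraries and at 15.3 ± 9.13 TPM in the 3 VCP TG libraries (adjusted p = 0.00124). Igkv2-95-2 entered the test only through the VCP TG libraries, so its p can be too small. Leaving out VCP TG replicate 1 or 2 gave 0 genes, and leaving out the library labelled WT replicate 1 or 3 gave 3. The groups did not overlap in 718 genes (5.13%), against 5.71% by chance. Nppa (-1.77 ± 1.43), Nppb (-0.56 ± 1.22), Myh6 (0.18 ± 0.21), Myh7 (0.20 ± 0.28), Acta1 (0.24 ± 1.15) and Atp2a2 (-0.16 ± 0.22) did not pass, nor did Col1a1 (adjusted p = 0.904).

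Whether the genotype difference changed with time was tested as VCP TG against WT at 5 weeks minus that at 2 weeks TAC. The 13 mitochondrially encoded subunits had a shift of 0.34, 12 of them above the median of all genes (camera adjusted p = 0.0177; adjusted p = 0.994 with an estimated correlation), with mt-Co1 at 0.34 ± 0.32 and mt-Atp6 at 0.28 ± 0.33. That call was lost under quantile normalization, with the receptor genes as a covariate and without the libraries whose Vcp goes against the label. The other 40 lists did not pass. By limma 1 of 16347 genes passed, Hbb-bh0 (adjusted p = 0.00128), and 323 genes had an unadjusted p under 0.05. At 2 weeks TAC Hbb-bh0 was at 3.60 ± 0.406 TPM in VCP TG and listed at 0 in WT. At 5 weeks TAC it was at 2.68 ± 2.11 in WT and listed at 0 in VCP TG. The groups at 0 lower its spread, so its p can be too small. Vcp stood at -1.15 ± 0.57 (adjusted p = 1). Nppa (-1.92 ± 2.75), Nppb (0.27 ± 1.39), Myh6 (-0.17 ± 0.42), Myh7 (-0.14 ± 0.50), Acta1 (-0.54 ± 1.23), Atp2a2 (-0.19 ± 0.39) and Col1a1 (-0.40 ± 0.73) did not pass. Across 13864 genes, the genotype differences at 2 and 5 weeks TAC correlated with r = 0.502 (rho 0.524), and those in sham and at 2 weeks TAC with r = 0.166 (rho 0.0532).

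**Figure D5:**
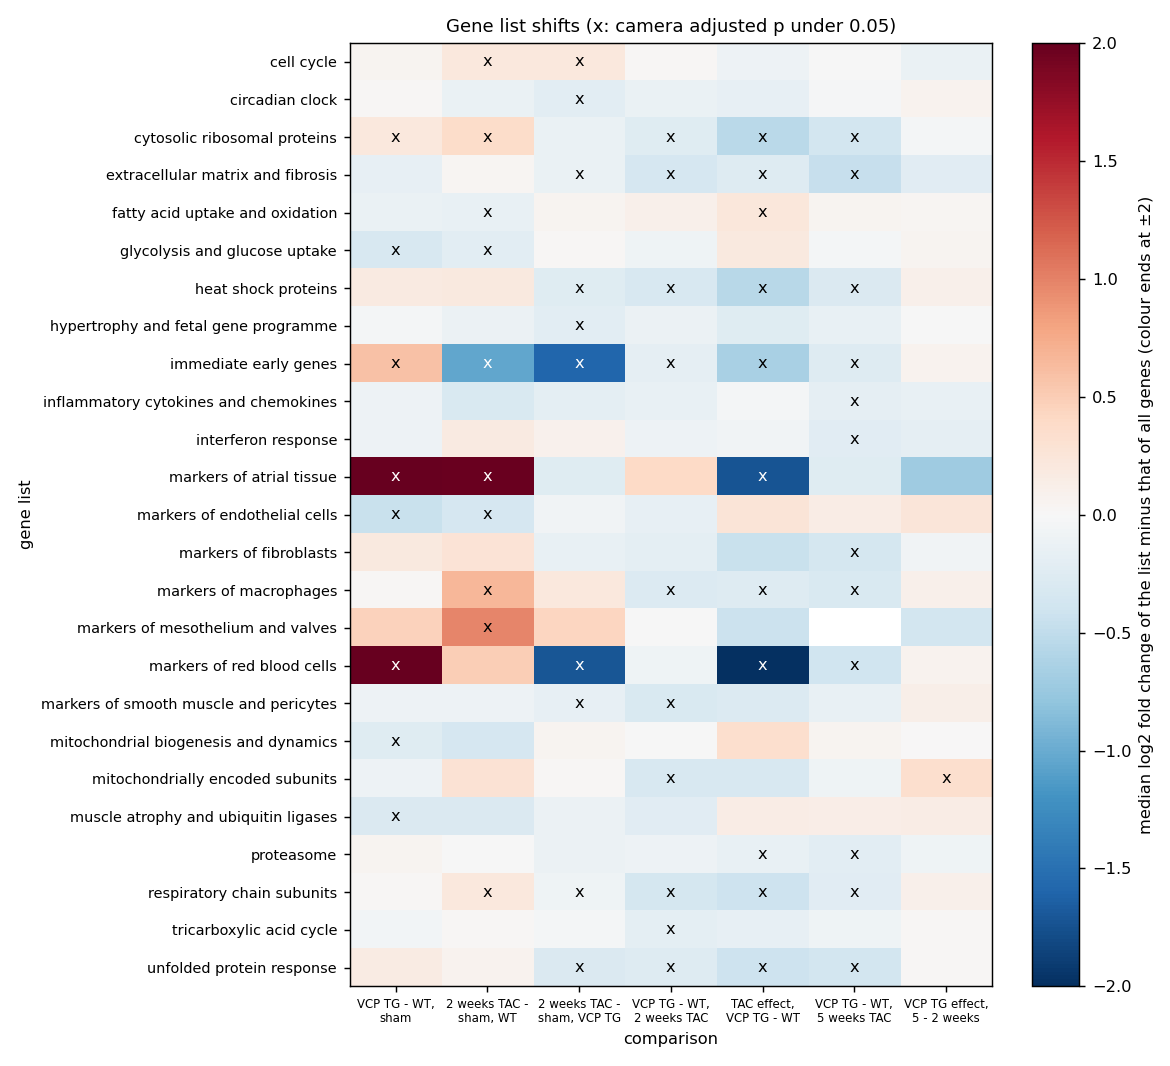
Median log2 fold change of each gene list minus that of all genes (colour, ending at ±2) for the 25 lists that passed camera in at least 1 of the 7 comparisons; x marks an adjusted p under the threshold, and a white cell a list with too few measured genes. Immediate early genes lie below 0 at 2 weeks TAC against sham in VCP TG (-1.58) and in WT (-1.04).

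Of the 41 lists, 16 passed in no comparison. Their smallest adjusted p was 0.0933 for endoplasmic-reticulum-associated degradation and VCP cofactors, 0.0537 for autophagy and lysosome, 0.0554 for antioxidant and NRF2 targets, 0.0615 for sarcomere and Z-disc, 0.0654 for mitochondrial calcium uptake and permeability transition and 0.0742 for apoptosis and p53 targets. It was 0.0904 for cardiomyocyte markers, 0.101 for adipocyte markers, 0.115 for mTOR and growth signalling, 0.119 for lymphocyte markers, 0.122 for sex-linked genes, 0.125 for TGF-beta and fibroblast growth signals and 0.143 for nitric oxide and cyclic GMP. For calcium handling and ion channels it was 0.150, for neutrophil and mast cell markers 0.357 and for nerve and Schwann cell markers 0.593.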

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

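The tests of Vcp, of read depth and of what goes beyond centring were chosen after the results were seen; those of genomic DNA, GC content, transcript length and other splits of the libraries were written down before they were run.

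The Vcp level of 5 libraries lay with the other genotype after rescaling to nuclear protein-coding genes. The large mitochondrial share is argued against for 4 of them, which lay there in TPM as deposited and stayed there after rescaling, but scaling stays open for VCP TG sham replicate 1 (89.1 TPM), out of place on the rescaled values alone. An exchange of genotype labels between libraries of 2 weeks TAC is argued against, as 0 pairs there were out of place in both genotypes. A wrong label of 1 library, or an exchange with a mouse outside that set, would give 0 pairs too and stays open. In sham 1 pair out of place in both genotypes was seen in TPM as deposited and 0 after rescaling, and at 5 weeks TAC 1 pair. With no other gene to mark the genotype an exchange stays open in sham and at 5 weeks TAC. Atrial tissue, if richer in Vcp, might account for the library labelled WT 2 weeks TAC replicate 1 (Myl7 1546 TPM), which stays open, but not for the libraries labelled WT 5 weeks TAC replicates 2 and 3, whose highest Myl7 was 6.71% of that. Transgene expression that varies between mice could account for the VCP TG libraries with low Vcp and was not tested.

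The 119 genes that rose at 2 weeks TAC in VCP TG held 92 (77.3%) that were not named protein-coding genes, against 16.6% of the genes tested (Fisher exact p = 1.6e-48 across genes, which are not independent replicates). Genomic DNA in the libraries could give this: 134 keratin-associated protein, beta-defensin and bitter taste receptor genes, not looked at before, had a mean of 0.305 ± 0.203 TPM in VCP TG sham and 0.721 ± 0.357 at 2 weeks TAC, a ratio of 2.36 (1.71 to 3.47 leaving out 1 library), and the groups overlapped, the highest sham library standing at 0.598. In WT the ratio was 1.93. Read depth is argued against, since depth alters how many receptor genes are seen but not their mean, and that mean had a ratio of 3.63 (2.59 to 5.66 leaving out 1 library). With the receptor level as a covariate the median log2 fold change of the 119 went from 1.67 (interquartile range 0.47, median standard error 0.34) to 0.73 (0.90, 0.41), 115 stayed above 0 and 0 passed. That level parts sham from TAC in VCP TG, so the covariate cannot tell background from an effect of load. A wide release of transcription under load in VCP TG hearts would raise the same genes and stays open, as no library made without reverse transcription was used here.

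The genes called in the 8 WT libraries fitted alone differed in GC content. The median was 55.8% in those that fell, 43.5% in those that rose and 49.9% in those not called. After the trend of each library with GC content was removed, 94 of 947 calls stayed; the median of the genes that fell went from -0.78 (interquartile range 0.25) to -0.49 (0.27) and its distance from the genes not called from -0.64 to -0.51. Trend removal also centres each library, and centring alone, run after these results were seen, left 413 calls and a distance of -0.64. Of the 853 calls lost with GC, 531 were lost under centring too, so the bound set before was met in part by centring. Of the 413, 91 stayed with the GC trend removed, between the bounds, so a GC bias between libraries may account for a part of the calls and stays open. With the trend with transcript length removed 365 calls stayed, the genes that fell went to -0.60 (0.25), the genes that rose from 1.01 to 1.14, and that distance was -0.63. Of the 582 calls lost there 497 were lost under centring too, and of the 413 calls 328 stayed, so length beyond centring is argued against. A response to load that is shared by GC-rich genes would lose calls in the same way, and the data cannot tell these apart.

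Counts of genes past the threshold were set against other ways to split the same libraries. Chance is argued against for the 8 WT libraries alone, where 1 of 35 splits, the real one, reached 964 and the highest other gave 5. A rank of 1 in 35 is the lowest possible, and no adjustment was made over these tests. The 964 calls also moved to between 49 and 2148 leaving out 1 library. At 2 weeks TAC between the genotypes 1 of 35 splits, the real one, reached 14 genes, but the highest other gave 13, a margin too small to exclude chance firmly. Chance was not excluded for VCP TG TAC against sham, where 3 of 35 splits reached 120 and the highest, 885, parted VCP TG sham replicates 1, 2 and 4 from the rest. Nor was it for the TAC effect between genotypes (21 of 100 splits reached 1 gene, highest other 3), the genotypes at 5 weeks TAC (15 of 35 reached 1, highest other 6) or the genotype difference at 5 against 2 weeks (24 of 100 reached 1, highest other 6). For WT TAC against sham the real split gave 0 genes, which all 35 reached, and the highest other gave 1. In sham the real split gave 0, all 35 reached that, and the highest other gave 154. The 8 sham splits that part all 4 pairs of equal replicate number gave at most 0 genes, the 24 that part 2 pairs up to 124, and the 3 that part none up to 154.

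In 10 of 60 tests, 15 measures in 4 groups of 4 libraries, 1 library stood apart from the other 3 by Dixon's criterion for 4 values, which chance meets in about 1 of 20. The genes measured were Vcp, Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Col1a1, Myl7, Hbb-bs and Ddx3y. The rest were the mitochondrial and Gm10800 shares of TPM, and the receptor genes' share above 0 and mean. Other measures were not tested this way. Myl7 was 55.6 TPM in WT sham replicate 3, against 0.773 to 9.11 in the others. In WT sham replicate 1, 14.4% of receptor genes were above 0 (others 28.5% to 31.4%), with a mean of 0.0525 TPM (others 0.0846 to 0.0888). VCP TG sham replicate 3 held 4864 TPM of Nppa (others 21.7 to 612) and 936 of Hbb-bs (others 50.5 to 125). The library labelled WT 2 weeks TAC replicate 1 held 119 TPM of Vcp (others 47.7 to 50.3), 5174 of Nppa (others 32.5 to 88.6), 345 of Nppb (others 56.3 to 104) and 1546 of Myl7 (others 3.34 to 30.3). Myh7 was 232 TPM in WT 2 weeks TAC replicate 2, against 173 to 174 in the others.

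Hbb-bh0 differed between the TAC effects of the genotypes by 2.20 and between the genotype effects at 5 and 2 weeks TAC by -3.81 on the log2 scale. The TAC effects also differed by the camera test in red blood cell markers (-2.41), atrial markers (-1.72), immediate early genes (-0.65), heat shock proteins (-0.55), ribosomal proteins (-0.53), respiratory chain subunits (-0.42), unfolded protein response (-0.41), extracellular matrix (-0.26), macrophage markers (-0.25), proteasome (-0.15) and fatty acid genes (0.22), none of which passed with an estimated correlation (adjusted p = 0.998 each). The atrial, immediate early, matrix, macrophage and fatty acid calls ended without the libraries rich in atrial genes. The genotype effect on mitochondrially encoded subunits differed between 5 and 2 weeks TAC by 0.34. That call was lost with an estimated correlation (camera adjusted p = 0.994) and under quantile normalization. It was also lost with the receptor covariate and without the libraries whose Vcp goes against the label. Of olfactory and vomeronasal receptor genes, which no comparison was planned on, every one of the 14 TAC libraries (lowest 58.7%) had more above 0 than every WT sham library (highest 31.4%), but VCP TG sham replicate 3 had 68.2%, within the range of the TAC libraries.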

How the results depend on the processing

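TPM holds no read number, so what depth limits cannot be stated, and tests on counts were not run. Counts not given here stayed within 1.5 times. Where no cause is named, the cause was not tested. VCP TG against WT in sham (0 genes) gave 1 with a pseudocount of 0.1, 2 with only the 2 groups compared, 2 without the libraries whose Vcp goes against the label, and 0 to 1 leaving out 1 library. WT TAC against sham (0) gave 2 with quantile normalization, 8 with a pseudocount of 0.1, 2 with the replicate block, 964 with only the 2 groups, 3 rescaled to nuclear protein-coding genes, 1202 without the libraries rich in atrial genes, 1 with the receptor covariate, 2 among named protein-coding genes and 0 to 1 leaving out 1 library. VCP TG TAC against sham (120) gave 1846 with no filter on low values, 6 at a minimum of 5 TPM, where fewer genes were tested, 2 and 210 with pseudocounts of 0.1 and 5, 53 with only the 2 groups, 184 rescaled, 17 without libraries against the label, 719 without atrial-rich libraries, 0 with the receptor covariate, 7 among named protein-coding genes and 1 to 753 leaving out 1 library.

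VCP TG against WT at 2 weeks TAC (14) gave 9 with quantile normalization, 634 with no filter, 1 at a minimum of 5 TPM, 1 and 28 with pseudocounts of 0.1 and 5, 5 with the replicate block, 8 with only the 2 groups, 9 without libraries against the label, 640 without atrial-rich libraries, 1 with the receptor covariate, 0 among named protein-coding genes and 1 to 15 leaving out 1 library. The difference of TAC effects (1) gave 2 with quantile normalization, 4 without trend, 24 with no filter, 0 at 5 TPM, 0 and 5 with pseudocounts of 0.1 and 5, 0 with the replicate block, 3 rescaled, 0 without atrial-rich libraries, 0 among named protein-coding genes and 0 to 4 leaving out 1 library. At 5 weeks TAC (1) a pseudocount of 5, the replicate block, dropping libraries against the label and testing named protein-coding genes each gave 0, and leaving out 1 library 0 to 3. The genotype effect at 5 against 2 weeks (1) gave 6 with no filter, 0 at 5 TPM, 2 with a pseudocount of 5, 0 without libraries against the label, 0 without atrial-rich libraries, 0 among named protein-coding genes and 1 to 2 leaving out 1 library.

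With the receptor covariate 3 lists turned: respiratory chain in VCP TG TAC (0.64) and at 2 weeks TAC between genotypes (0.28), and tricarboxylic acid cycle at 2 weeks TAC (0.40). In both comparisons the receptor level parts the groups, so these turns cannot show that background was the cause. With an estimated correlation, and with fry, all 62 list calls were lost. Leaving out any 1 library kept 27 of the 62 under the preset correlation. In sham these were red blood cell, atrial and endothelial markers, and in WT TAC immediate early, macrophage and ribosomal genes. In VCP TG TAC they were immediate early, red blood cell, unfolded protein response, heat shock, clock and hypertrophy genes. Ribosomal, respiratory chain and unfolded protein response genes were kept between genotypes at 2 and 5 weeks TAC and in the difference of TAC effects. So were heat shock and mitochondrially encoded genes at 2 weeks, and matrix and proteasome genes at 5 weeks. In the difference of TAC effects heat shock and red blood cell genes were kept too. Leaving out 1 library, values of named genes moved by more than 1.5 times in 33 of 39 in sham, 14 of 47 in WT TAC, 26 of 55 in VCP TG TAC, 19 of 49 at 2 weeks TAC, 25 of 51 in the difference of TAC effects, 32 of 55 at 5 weeks TAC and 11 of 13 at 5 against 2 weeks. Of these values leaving out 1 library, 2699 stayed called or uncalled as before, 6 gained a call and 30 lost it. Direction was compared only for genes called in either fit, and some of the others changed sign. In sham, where equal numbers deviated together (2 of 4 best with its own number), the replicate block changed no call but that of immediate early genes. That block also covered the TAC libraries of the 2-week table, so it did not test pairs in sham alone. Elsewhere the numbers are only shared. There the block ended the list calls of matrix in VCP TG TAC, mitochondrially encoded and immediate early genes at 2 weeks TAC between genotypes, matrix, fatty acid and macrophage genes in the difference of TAC effects, and macrophage, interferon, immediate early and red blood cell genes at 5 weeks TAC. There the correlation of equal numbers was -0.06 to 0.09 in WT TAC (1 of 4 best with its own number), -0.23 to 0.03 in VCP TG TAC (0 of 3), -0.13 to 0.06 at 2 weeks TAC (0 of 3) and -0.22 to 0.16 at 5 weeks TAC (1 of 3).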

Other observations

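Some genes passed only when adjusted over their own list, and their lists did not pass. That adjustment did not extend over the lists or the comparisons, so some such calls can arise by chance. Over all genes tested, the smallest limma adjusted p in sham was 0.735. In sham hearts the death receptor Fas stood lower in VCP TG (-1.49 ± 0.34, limma adjusted p = 0.00743 over the 23 apoptosis and p53 genes alone) and the clock output factor Hlf higher (1.18 ± 0.29, adjusted p = 0.00979 over the 18 clock genes alone), with all 4 VCP TG libraries above all 4 WT libraries for Hlf and overlap for Fas. At 2 weeks TAC in VCP TG, Irs2, which carries the insulin signal, stood lower than in sham in all 3 libraries (-1.71 ± 0.42, adjusted p = 0.0185 over the list alone). The cystine transporter Slc7a11 (1.28 ± 0.34) and the NADPH oxidase Nox4 stood higher (adjusted p = 0.0245 each over the list alone), with groups that overlapped. At 2 weeks TAC the lymphocyte gene Cd8a (1.05 ± 0.31, adjusted p = 0.0152) and the neutrophil receptor Cxcr2 (adjusted p = 0.0224) stood higher in all 3 VCP TG libraries than in the 4 WT libraries, and over all genes the adjusted p of both was 0.167.

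The library labelled WT 5 weeks TAC replicate 4 held 0.192 TPM of Ddx3y and 3.66 of Uty, genes of chromosome Y, while the other 21 libraries held 11.1 to 21.3 and 9.41 to 27.6. It held 1.43 TPM of Eif2s3y (others 13.4 to 27.0) but 6.98 of Kdm5d (others 7.46 to 30.2), so 3 of the 4 genes are far below the others and 1 is just below, which leaves the sex of this mouse in doubt. Without it 1 gene passed between the genotypes at 5 weeks TAC, as with it, and the macrophage, interferon, immediate early and red blood cell list calls were lost. Across 13864 genes, which are not independent replicates, the genotype differences in sham and at 5 weeks TAC correlated with r = -0.0866 (rho -0.179).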
